A study of Mus musculus with 2 samples.

How the data were processed

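The series holds 2 single-cell 3′ RNA libraries of mouse CD4+ YFP+ cells, 1 from Il17Cre/R26YFP mice (control) and 1 from Il17Cre/Id2f/f/R26YFP mice (Id2-deficient). The files are the deposited counts, UMI counts per gene and cell barcode written by Cell Ranger; per the file headers the version was 5.0.1, while per the submitters' processing notes it was 1.3. The genome build, per the same notes, was mm10. The deposited barcodes had already been filtered, and neither the rule used nor whether it was the same for both libraries is given in the sources used here. The labels disagree on the tissue: sample titles name draining lymph node, the source and tissue fields name spleen and lymph node together, and the protocol names spleen. How many mice went into each library, and which exons of Id2 are floxed, is not given in the sources used here. The labels name version 2 of the kit, but the deposited barcodes begin as those of version 3 do; the lists of allowed barcodes were not at hand, so the version is left open.

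Both tables hold the same 32285 genes, of which 40 symbols occur more than once; genes were kept apart by Ensembl ID. Coordinates came from the GENCODE M21 annotation of GRCm38, which held 32158 of these IDs. The median barcode had 5448 UMIs in the control and 5643 in the Id2-deficient library, and 3 barcode sequences occurred in both libraries. Barcodes were kept with at least 200 genes and at most 10% of UMIs from mt- genes. This removed 12 control barcodes (3 over the mt- limit and 9 under the gene limit) and 525 Id2-deficient barcodes (525 over the mt- limit, 5 of them also under the gene limit). Scrublet, run per library through scanpy, marked 2 control cells (0.0406%) and 9 Id2-deficient cells (0.465%), far too few for libraries of this size, so the automatic threshold had not worked and doublets were largely not removed; an alternative takes out the 4% of cells with the highest scores. After these steps 4923 and 1925 cells were left.

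Clusters were made from both libraries together without integration (scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, Python 3.11.15). Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.8 were used. The variable genes left out mt- and ribosomal protein genes, T cell receptor and immunoglobulin segments, Xist, Y-linked genes and Id2. There were 14 clusters. A cluster took the name of a cell class when at least 3 of that class's markers were among its 50 leading genes, with no tie and no other class ahead among the 10 leading genes. Leading genes were ranked by fold over the other cells with 20 CPM added, among genes with a UMI in at least 10% of the cluster's cells. The marker lists were fixed before the data were examined, but the ranking was set after a first look at the clusters, because globin genes from 1 cell had led a cluster. Of the marker symbols 2 were missing from the tables, as was 1 gene list symbol. Cells of B cell-like and neutrophil-like clusters were left out, and the remaining cells are called T-lineage cells. A cluster that stayed unnamed, with leading genes of B, plasma, red and myeloid cells, was kept among them (108 control and 27 Id2-deficient cells).

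UMIs were summed over the T-lineage cells of each library and divided by the library's sum to give CPM (UMIs per 1000000 UMIs of the library). A gene was measured if it had at least 50 UMIs over both libraries, which held for 11186 genes. The log2 ratio is that of Id2-deficient over control CPM, with an exact conditional binomial interval; where 1 library had 0 counts, a floor of 3 counts was used and the fold is given as a minimum. Each gene list was summarised by the median log2 ratio of its measured members, with an interval from 1000 Poisson resamples of the counts. Its percentile is among 10000 lists in which each member was replaced by 1 of the 100 measured genes nearest in expression, mt- and ribosomal protein genes not being drawn. There were 24 lists: Id and E proteins, Th17, Th1 and cytotoxic, Tfh, Treg, naive and central memory, glycolysis, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, tricarboxylic acid cycle, mitochondrial biogenesis and dynamics, fatty acid oxidation, fatty acid and cholesterol synthesis, amino acid uptake and one-carbon metabolism, Myc and ribosome biogenesis, cell cycle, interferon response, immediate early and dissociation stress, T cell receptor activation, inhibitory receptors, migration and adhesion, apoptosis and survival, antioxidant defence, and γδ T cell. Some lists share genes, such as Cxcr5 and Icos.

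Except where stated, the genes named were chosen by a rule fixed before the data were examined. It takes Id2, the 12 genes with the highest lower bound and the 12 with the lowest upper bound of the ratio. It also takes up to 4 members of each list. These are its highest and lowest member with an interval that excludes 0 and up to 2 further members at least 1.5-fold apart by UMI count. The rule did not select Bcl6, Ifng, Il17a, Il17f, Il22 and Foxp3, whose ratios are also given. They belong to the 20 genes fixed for shares of cells. Predicted gene models, mt- and ribosomal protein genes, T cell receptor and immunoglobulin segments, Xist and Y-linked genes were left out of the ranking over all genes. The lists, the 20 genes whose shares of cells were taken, and the comparisons were fixed at the same time; the values of some genes are not reported here. Shares of cells were taken after each cell was thinned to 1000 UMIs without replacement. Within clusters, genes were measured with at least 20 UMIs, and clusters with at least 100 cells of each library were used. For class shares, clusters were also made after leaving out the 953 genes whose CPM, with 1 added, differed at least 2-fold between the libraries.

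Alternatives planned in advance were: no cell filter; a stricter filter (500 genes, 5% mt-); doublet calls kept or the highest scores removed; all cell classes; totals without mt- and ribosomal protein genes; centring on the median gene; equal weight per cell; thinning; averaging within clusters; a minimum of 20 or 200 UMIs; means in place of medians; thinning to 500 or 2000 UMIs or none; resolutions 0.5 and 1.2; another seed; and clusters without differing or cell cycle genes. Others were added after the data were seen: a gate on T cell receptor and CD3 UMIs, cells with 2% to 3% mt- UMIs (1323 control and 232 Id2-deficient), leaving out the γδ T cell-like cluster, averaging within clusters made without differing genes, the genes that lead the difference within the γδ T cell-like cluster, and class shares under other cell filters and doublet treatments.

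The procedure was tested on simulated data, in which 200 genes and the Tfh list were given known differences at the depth of these libraries and 11015 measured genes were left alone. Of genes raised or lowered 4-fold, 33 of 33 and 31 of 31 had an interval on the right side of 0, and of those raised or lowered 1.5-fold 33 of 34 and 27 of 32. The intervals held the true ratio for 95.3% of the genes left alone. The Tfh list, raised 2-fold, gave a median log2 ratio of 0.97 at percentile 100, and 1 of 23 lists left alone lay outside the central 95%. The simulated counts were independent Poisson draws from summed counts, without variation between cells, so a coverage near 95% was built in. These rates do not carry over to genes whose UMIs lie in few cells, or to list members that vary together. No test across mice was made, because each genotype has 1 library, and differences between cells were not tested, because cells are not replicates.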

Results

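The data are single-cell transcriptomes of CD4+ YFP+ cells sorted from mice with experimental autoimmune encephalomyelitis, a model of multiple sclerosis. The disease was induced with a myelin antigen (MOG) in complete Freund's adjuvant, and cells were taken at its peak. In these mice Cre recombinase is driven from Il17 and switches on YFP from the Rosa26 locus, so that YFP marks cells with a history of interleukin 17 expression. There was 1 library from mice with this reporter alone (control) and 1 from mice that also carried floxed Id2 alleles (Id2-deficient). The series title names Id2 as a metabolic checkpoint in the fate of Th17 cells, the helper T cells that make interleukin 17. The control library held 4937 barcodes and 33646845 UMIs, and the Id2-deficient library 2459 barcodes and 14668624 UMIs. Barcodes ranged from 505 to 87398 UMIs in the control and from 513 to 57577 UMIs in the Id2-deficient library. After filtering, 4841 control and 1885 Id2-deficient T-lineage cells were compared, with 32835265 and 13801675 UMIs. Their median depth was 5458 and 6359 UMIs, and 1.75% and 4.18% of the UMIs of the median cell came from mitochondrially encoded (mt-) genes. With 1 library per genotype no difference has a replicate check, and every 95% interval covers counting error only.

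The targeted gene was asked first, as a check of the labels. Id2 (ENSMUSG00000020644; chromosome 12, 25093799 to 25097140, minus strand, GRCm38) encodes an inhibitor of DNA binding that keeps E-protein transcription factors from their sites. It gave 10959 UMIs in the control and 185 in the Id2-deficient library, or 334 CPM (exact Poisson interval 328 to 340) and 13.4 CPM (11.5 to 15.5). Id2 was therefore 24.9-fold lower (21.5 to 29.0) in the Id2-deficient library. At least 1 Id2 UMI was seen in 66.7% of control cells (Clopper-Pearson interval 65.3% to 68.0%) and in 3.13% of Id2-deficient cells (2.39% to 4.02%). The labels do not name the floxed exons, and a 3′ library counts the end of the transcript, so the count checks the label only if that end is lost with the deletion. Among cells with 2% to 3% of their UMIs from mt- genes, a selection made after the data were seen, the log2 ratio was −3.83, against −4.64 over all T-lineage cells.

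Over the whole transcriptome, the 12 genes with the largest excess in the Id2-deficient library included 1 of the list fixed for follicular helper T (Tfh) cells, which help B cells. That gene, Cxcr5 (ENSMUSG00000047880; chromosome 9, 44511787 to 44561877), the chemokine receptor that guides cells into follicles, was 6.58-fold higher (5.85 to 7.41), at 77.4 CPM against 11.8 CPM. Il21 (ENSMUSG00000027718; chromosome 3, 37222759 to 37232636), a cytokine that acts on B cells, was 5.90-fold higher (5.16 to 6.76). Id3 (ENSMUSG00000007872; chromosome 4, 136143497 to 136145755), the relative of Id2 with a similar action on E proteins, was 5.33-fold higher (4.99 to 5.69), at 208 CPM against 39.0 CPM. Ly6c1, a surface antigen, was 6.18-fold higher (5.25 to 7.28). The highest lower bound belonged to Insyn2b, which gave 91 UMIs against 9 and was 24.1-fold higher (12.1 to 54.3). Kcnf1, a potassium channel subunit that lies 7.92 Mb from Id2 on chromosome 12, was 10.9-fold higher (6.87 to 17.9). Slc16a5, of the monocarboxylate transporter family, was 9.25-fold higher (6.60 to 13.2). The other highest genes were Chn1, Olfr524, Degs2, Drc1 and Ppic, with log2 ratios of 3.74, 3.15, 3.45, 3.20 and 2.94.

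On the low side, Ifitm1 (ENSMUSG00000025491; chromosome 7, 140967221 to 140969825), an interferon-induced membrane protein, was 68.0-fold lower (42.4 to 117) and was seen in 458 control and 11 Id2-deficient cells. The rest of the 12 lowest genes were those of red cells (Car1, Hbb-bs, Hbb-bt, Hba-a1, Hba-a2), basophils or mast cells (Prss34, Mcpt8), granule-bearing myeloid cells (Prtn3, Ctsg, Elane) and the chemokine gene Ccl1. For 9 of the 12 more than 50% of the control UMIs lay in 1 cell; Car1, Prss34, Mcpt8, Ctsg and Elane had 0 UMIs in the Id2-deficient library, and Prtn3 and Ccl1 had 1 each. When only cells with at least 3 T cell receptor or CD3 UMIs were kept (4726 and 1851 cells, an alternative chosen after the data were seen), and genes with 10% or more of their UMIs in 1 cell were left out, 9 of the 12 highest genes and 1 of the 12 lowest were shared with the first ranking. In that ranking the lowest genes included Ifitm1 (log2 ratio −6.13), Id2 (−4.81), Stmn2 (−4.57), Cx3cr1 (−5.80; 3 UMIs against 391, interval −8.09 to −4.24), the cytotoxic granule gene Nkg7 (−3.66), Ifitm2 (−3.54) and Mal (−3.76). The transcription factor genes Myb (2.66) and Cebpa (2.80) joined the highest genes there. Over all 11186 measured genes the median log2 ratio was 0.08, and 5% and 95% of the genes lay at −0.99 and 1.09.

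The helper T cell programs were compared next, as gene lists fixed beforehand. Of the 17 Tfh genes, 17 were at least 1.5-fold higher in the Id2-deficient library, with a median log2 ratio of 1.70 (counting interval 1.59 to 1.82). Besides Cxcr5, they included the signalling adaptor gene Sh2d1a (1.16), the costimulatory genes Slamf6 (1.57) and Tnfsf8 (1.57), the master regulator Bcl6 (1.86) and the inhibitory receptor gene Pdcd1 (1.45). Of 21 measured genes of the Th1 and cytotoxic program, 15 were at least 1.5-fold lower and 0 higher, with a median of −1.71 (−2.03 to −1.40). Nkg7 was 12.6-fold lower (10.8 to 14.7), Ifng, the signature cytokine of Th1 cells, 11.0-fold lower (8.05 to 15.4), and the chemokine receptor gene Cxcr6 3.27-fold lower (3.12 to 3.44); Stat4, which relays interleukin 12 signals, was slightly higher (log2 ratio 0.36). Among 10000 expression-matched random lists, the Tfh median lay at percentile 100 and the Th1 median at percentile 0. Averaged within the 4 clusters that held at least 100 cells of each library, the medians were 0.18 for 9 Tfh and −0.37 for 9 Th1 genes, which stood at 1.57 and −0.70 over all cells, and Pdcd1 was −0.36. Within clusters made without the genes that differ 2-fold they were 0.40 for 6 Tfh and −0.11 for 7 Th1 genes. Among cells with 2% to 3% of mt- UMIs they were 0.85 and −0.91, with Stat4 at −0.11, but that window kept 43.2% of control and 8.95% of Id2-deficient Tfh-like cells, so it also changes the mix of cell states in each library.

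The Th17 program went both ways. Of 19 measured genes 5 were at least 1.5-fold higher and 4 lower, and the median log2 ratio was 0.13 (−0.03 to 0.26), at percentile 83.3 of the random lists. The ion channel-like genes Tmem176b and Tmem176a, abundant in Th17 cells, were 2.43-fold (2.34 to 2.52) and 2.10-fold lower (2.03 to 2.17). Il17a, the cytokine gene that defines these cells, stood at −0.54 (−0.89 to −0.21), whereas Il17f stood at 0.41 (0.22 to 0.60) and Il22 at 0.69 (0.53 to 0.85). Single cells weigh on these cytokine values: 1 cell held 52.4% of the control UMIs of Il22, 1 held 25.9% of those of Il17f, and 1 held 24.2% of the Id2-deficient UMIs of Il17a. The transcription factor gene Maf was 1.79-fold higher (1.74 to 1.84), and Il21, which Tfh cells make too, was the highest member of the list. With cells thinned to 1000 UMIs the list median was 0.42, with no cell filter 0.27, and averaged within clusters −0.00.

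Naive and central memory genes were higher in the Id2-deficient library as a group. Of 18 genes 12 were at least 1.5-fold higher and 3 lower, with a median log2 ratio of 0.76 (0.66 to 0.83) at percentile 100. Tcf7, a regulator of memory and Tfh cells, was 1.79-fold higher (1.73 to 1.85), and Dapl1 4.19-fold higher (3.13 to 5.64). Klf2, which keeps cells recirculating, was 3.21-fold lower (3.12 to 3.31), and Il7r, the interleukin 7 receptor chain, 2.10-fold lower (2.04 to 2.16). The Treg program had 4 of 13 measured genes at least 1.5-fold higher and 2 lower (median 0.20, percentile 91.9); the folate receptor-like gene Izumo1r (1.97), Ikzf2 (1.54) and Nt5e (0.66) were higher and Capg (−1.05) lower, while Foxp3 was 0.20 (−0.34 to 0.73). Averaged within clusters the naive and memory median was 0.14 and Tcf7 −0.02, and among cells with 2% to 3% of mt- UMIs these were −0.18 and −0.28, with Izumo1r at −0.04. Nt5e was lower in both (−0.49 and −0.51), and the Treg median was −0.0123 within clusters made without the genes that differ 2-fold.

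Because the series title speaks of metabolism, the metabolic lists were asked as a group of their own. Glycolysis genes went both ways, with 3 of 25 at least 1.5-fold higher, 5 lower and a median log2 ratio of −0.08 (−0.17 to −0.02), at percentile 24.4. The first enzyme of the pathway, Hk2, was 2.12-fold lower (1.73 to 2.63), Eno1 1.74-fold lower (1.67 to 1.81) and the lactate dehydrogenase gene Ldha 1.52-fold lower (1.47 to 1.56). In contrast Pdk1, a kinase that inhibits pyruvate dehydrogenase, was 2.93-fold higher (2.63 to 3.26). Nuclear-encoded oxidative phosphorylation genes had a median of −0.22 (−0.24 to −0.20), at percentile 8.78; 3 of 77 were at least 1.5-fold lower (Uqcrfs1 −0.81, Cox5a −0.67, Ndufs5 −0.61) and 0 higher, with Cox7a2l highest at 0.58. The 13 mitochondrially encoded genes went the other way, with 11 at least 1.5-fold higher and a median of 1.10 (1.09 to 1.11), at percentile 100; mt-Atp6 was 3.27-fold higher (3.25 to 3.30), mt-Co2 2.14-fold (2.12 to 2.16) and mt-Nd6 3.51-fold (3.07 to 4.01), and mt-Nd4l was 1.29-fold lower (1.25 to 1.32). The cell filter, set mainly by mt- RNA, removed 21.4% of Id2-deficient and 0.243% of control barcodes, and whether both libraries had been filtered alike before deposit is not given. Among cells with 2% to 3% of mt- UMIs the medians were 0.08 for glycolysis, with Ldha at 0.08, 0.07 for nuclear-encoded and 0.17 for mitochondrially encoded genes, the last set by that selection.

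Lipid genes showed a mixed picture. Fatty acid and cholesterol synthesis had 8 of 28 measured genes at least 1.5-fold lower and 5 higher, with a median of −0.25 (−0.35 to −0.11), at percentile 0.03. Within single clusters its median went both ways, as given below. The isoprenoid enzyme genes Idi1 and Fdps were 2.10-fold (1.80 to 2.46) and 1.505-fold lower (1.36 to 1.66), while the desaturase gene Scd2 was 3.26-fold higher (2.91 to 3.65) and Acly, which makes cytosolic acetyl-CoA, 1.52-fold higher (1.38 to 1.67). Fatty acid oxidation had a median of −0.17 (−0.25 to −0.05), at percentile 2.06, with 1 of 18 genes at least 1.5-fold lower, the acyl-CoA dehydrogenase gene Acadl (2.002-fold, 1.85 to 2.17), and Decr1 at 0.48. The tricarboxylic acid cycle (0.04), mitochondrial biogenesis and dynamics (0.05), amino acid uptake and one-carbon metabolism (0.06), and Myc and ribosome biogenesis (−0.02) had medians within the central 95% of random lists. In these lists Idh3a (−0.94), Idh1 (−0.80), Glud1 (−0.82), Odc1 (−0.66), Myc (−0.66) and Timm23 (−0.45) were lower, and Cs (0.40), Polg (0.75), Slc38a1 (0.82) and Polr1a (0.55) higher. Antioxidant genes had a median of −0.23, at the lower end of the central 95% of random lists, with Sod1 at 1.07 and Gsr (−0.89), Prdx4 (−0.85) and Prdx6 (−0.64) lower. Averaged within clusters Acadl's list kept its sign, but Decr1 was −0.33, Scd2 0.30 and Idh3a −0.10; among cells with 2% to 3% of mt- UMIs Idi1 was −0.01, Decr1 −0.43, Timm23 0.06 and Prdx4 0.10.

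**Figure D1:**
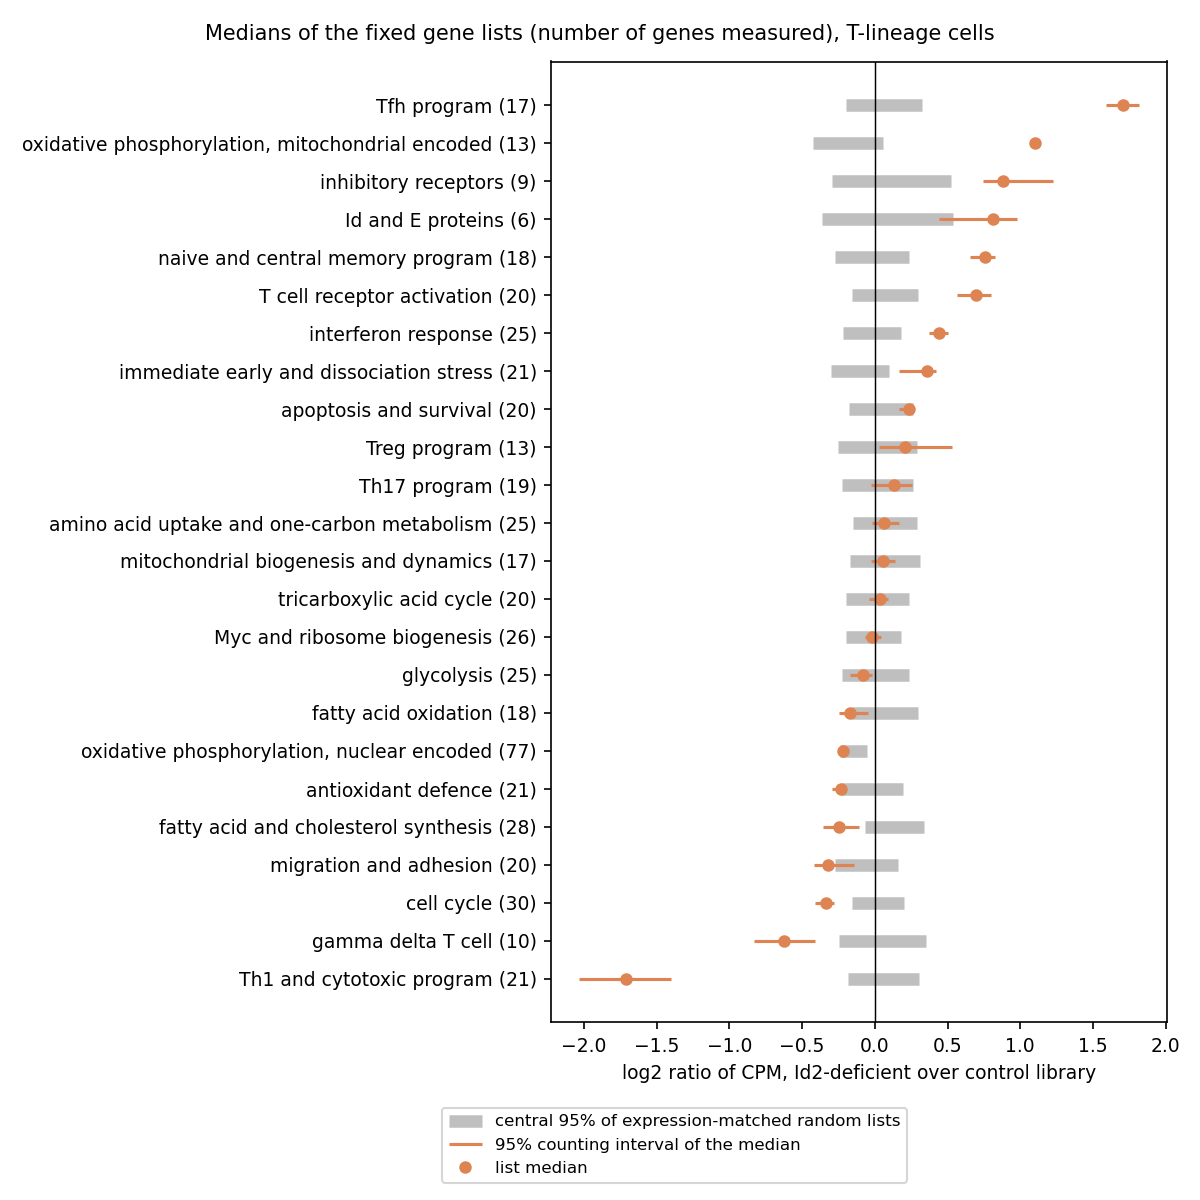
Median log2 ratio of CPM (x axis, Id2-deficient over control library) for each of the 24 gene lists (y axis, number of measured genes in parentheses) over T-lineage cells. Points are list medians, lines their 95% counting intervals, and grey bars the central 95% of expression-matched random lists; the Tfh list lies at 1.70 and the Th1 and cytotoxic list at −1.71.

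Genes of activation and response were higher in the Id2-deficient library. Of 20 measured T cell receptor activation genes 11 were at least 1.5-fold higher and 0 lower (median 0.69, percentile 100), among them Egr3 (2.20), Icos (1.24) and Cd28 (0.90), with Tnfrsf18 at −0.52. Of 9 inhibitory receptor genes 6 were at least 1.5-fold higher and 2 lower (median 0.88, percentile 99.98); Btla was 3.26-fold higher (2.94 to 3.61) and Ctla4 2.496-fold higher (2.28 to 2.73), and Havcr2, found on terminal effector cells, was 3.34-fold lower (2.12 to 5.54). Interferon response genes had 9 of 25 at least 1.5-fold higher and 1 lower (median 0.44, percentile 100), with Usp18 at 1.81, Ifi27l2a at 1.03, Slfn5 at 0.73 and Ly6c2 at −1.15. Immediate early and dissociation stress genes had 7 of 21 higher and 1 lower by that size (median 0.36, percentile 100), with Egr1 at 2.00, the heat shock gene Hspa1b at 1.78, Jun at 1.14 and Ier2 at −0.81. Within clusters the activation median was 0.01, the inhibitory receptor median 0.33 over 3 genes, Cd28 −0.11 and Ifi27l2a −0.04. Among cells with 2% to 3% of mt- UMIs the medians were 0.32 for activation, 0.46 for inhibitory receptors and −0.02 for immediate early genes, with Slfn5 at −0.30 and Ly6c2 at 0.53.

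Cell cycle and γδ T cell genes were lower in the Id2-deficient library, and the other groups of this paragraph went both ways or were higher. Cell cycle genes had 9 of 30 at least 1.5-fold lower and 0 higher (median −0.34, percentile 0.01), with Birc5, Ube2c and Stmn1 at −1.10, −0.91 and −0.86 and Mcm2 at 0.32. Migration and adhesion genes had 8 of 20 lower and 5 higher by that size (median −0.32, percentile 0.70), with Ccr1 at −2.16, the integrin genes Itgb1 and Itgb7 at −1.43 and −0.80, and Cxcr5 as the highest member. Genes of γδ T cells had 5 of 10 lower and 0 higher (median −0.63, percentile 0), with Tcrg-C1, Blk and Tcrg-C2 at −1.07, −1.03 and −0.96 and Il1r1 at 0.45. Apoptosis and survival genes had a median of 0.23, at percentile 94.7, with the death receptor gene Fas at 1.37 and Bbc3 (−0.95), Bad (−0.78) and Pmaip1 (−0.67) lower. Id and E proteins, a list of 6 measured genes that includes the target, had a median of 0.81, with Id3 highest, Tcf12 at 1.16 and Id1 at 1.14; Id1 was −0.03 when all cell classes were kept. The cell cycle median was 2.996 among cells with 2% to 3% of mt- UMIs, with Birc5, Ube2c and Stmn1 at 3.98, 4.36 and 3.03, and −0.11 with the stricter cell filter; the 2% to 3% window kept 3.46% of control and 42.9% of Id2-deficient cycling cells. The γδ median was 0.47 within clusters, over 2 genes, and −0.26 without the γδ T cell-like cluster, an alternative chosen after the data were seen, and the apoptosis median was −0.00 within clusters. Pmaip1 was 0.57 in the 2% to 3% window and −0.0472 within clusters.

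Shares of cells with a UMI were compared after every cell was thinned to 1000 UMIs, which left out 22 control and 11 Id2-deficient cells. Cxcr5 was seen in 1.70% of control (Clopper-Pearson interval 1.36% to 2.11%) and 7.42% of Id2-deficient cells (6.27% to 8.70%), and Bcl6 in 0.934% (0.682% to 1.25%) and 3.36% (2.59% to 4.28%). Pdcd1 was seen in 3.28% and 7.68%, Tcf7 in 23.9% and 37.1%, and Il22 in 0.892% and 1.92% of cells. Lower in the Id2-deficient library were Cxcr6 (32.1% and 10.4%), Ifng (2.49% and 0.374%), Tbx21, the Th1 regulator (0.913% and 0.0534%), and Id2 (25.6% and 0.854%). For Il17a (0.581%, 0.386% to 0.839%, and 0.480%, 0.220% to 0.910%), Il17f (1.08% and 1.17%), Il23r (2.03% and 2.67%), Foxp3 (0.311% and 0.480%) and Mki67 (3.55% and 2.67%) the intervals overlapped, and a difference was not detectable at this depth. Il10 was seen in 1 control cell and in 0 of 1874 Id2-deficient cells, and Il17a with Ifng likewise. Unthinned, the shares were 5.66% and 30.7% for Cxcr5, 8.08% and 1.11% for Ifng, 2.77% and 1.91% for Il17a, 0.227% and 0.0531% for Il17a with Ifng, and 66.7% and 3.13% for Id2. For Il10 they were 0.0207% and 0.159%, and for Foxp3 1.24% and 0.796%, both the other way round from the thinned cells.

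B cell-like cells served as a background for free RNA. They numbered 41 in the control and 38 in the Id2-deficient library, with median depths of 3638 and 4923 UMIs. Thinned alike, they showed Cxcr5 in 0% and 5.26%, Bcl6 in 0% and 2.63%, Ifng in 0% and 2.63%, Id2 in 2.44% and 0%, and Pdcd1 and Tcf7 in 0% of cells in both libraries. B cells themselves express Cxcr5, Bcl6, Ccr6 and Ccr7. Ccr6 (13.03% and 10.9% of T-lineage cells) stood against 12.2% and 5.26% in B-like cells, and Ccr7 (2.51% and 4.38%) against 7.32% and 5.26%. Since B cells express these genes, their shares in B-like cells measure no free RNA and set no background. In T-lineage cells the intervals overlapped for Ccr6 (12.1% to 14.0% and 9.56% to 12.4%). For Ccr7 they did not (2.09% to 2.99% and 3.49% to 5.40%). Csf2, a cytokine gene of encephalitogenic T cells, was seen in 0.934% (0.682% to 1.25%) of control and 0.107% (0.0129% to 0.385%) of Id2-deficient T-lineage cells. Unthinned, its shares were 6.24% and 1.01%. Its shares in B-like cells were 2.44% and 0%, from too few cells to set a background. The Ifng share of Id2-deficient T-lineage cells lay below the 2.63% of their B-like cells, which is 1 cell.

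Clusters were formed from both libraries together to ask which cell states each library held. Since genes that differ between the libraries can draw cells apart, shares are given from clusters made without the 953 genes that differed at least 2-fold, with the share from all variable genes after it. The names of these clusters still came from all genes, the 953 included. The named shares are thus not independent of the gene list differences. Tfh-like cells made up 10.0% of control (9.21% to 10.9%) and 51.6% of Id2-deficient cells (49.4% to 53.9%), and 11.9% and 54.5% with all genes. Most of them lay in 1 cluster, with 716 of the 994 Id2-deficient cells, or 802 of 1050 with all genes, that had 1 Tfh marker among its 10 leading genes. With all genes, the Id2-deficient cells of this cluster 1 held less Pdcd1 (61.0 against 463 CPM), Bcl6 (33.0 against 130 CPM) and Cxcr5 (91.2 against 231 CPM) than those of the other Tfh-like cluster, cluster 5. Th1 or cytotoxic-like cells made up 15.4% (14.4% to 16.5%) and 0.779% (0.437% to 1.28%), and 22.4% and 0.675% with all genes. Cells of the γδ T cell-like cluster, led by Trdc, Blk and Tcrg-C2, made up 15.3% (14.3% to 16.3%) and 6.75% (5.67% to 7.97%), and 16.6% and 6.75% with all genes. Th17-like cells made up 10.3% (9.42% to 11.1%) and 2.18% (1.58% to 2.94%), and 28.2% and 2.34% with all genes. Naive or central memory-like cells made up 13.04% and 21.4%, interferon response-like cells 12.1% and 6.70%, cycling cells 6.32% and 5.45%, and Treg-like cells 0.772% and 0.883%. Clusters left unnamed held 15.1% of control and 2.18% of Id2-deficient cells. The larger, picked out after its values were seen, was led by Ifitm1 and Ifitm2 and held 639 control and 13 Id2-deficient cells. Ctla2a, Tsc22d3, Stmn2, St6galnac1, Cysltr1 and Iqgap2 were also among its 10 leading genes and among those of the Th17-like cluster made with all genes. The lower Th17-like share of control cells here may thus reflect naming, and the cells in common were not counted.

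Some of these shares depended on the clustering. The γδ difference ran from −8.50 to −11.1 percentage points over all settings run. Tfh-like cells were in excess in the Id2-deficient library in every setting run, least at Leiden resolution 1.2 (10.6 points, where 57.0% of Id2-deficient cells were unnamed), and Th1-like cells were fewer in every setting, least with no cell filter (−2.35 points). The Th17-like difference ran from −2.03 with doublet calls kept to −29.1 at resolution 0.5, and no cluster took that name without cell cycle genes. Naive or central memory-like cells were fewer in the Id2-deficient library under the stricter filter (−2.42 points) and with doublet calls kept (−3.63), and interferon response-like cells were in excess with all genes (1.26% and 3.69%), so neither was given a direction.

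**Figure D2:**
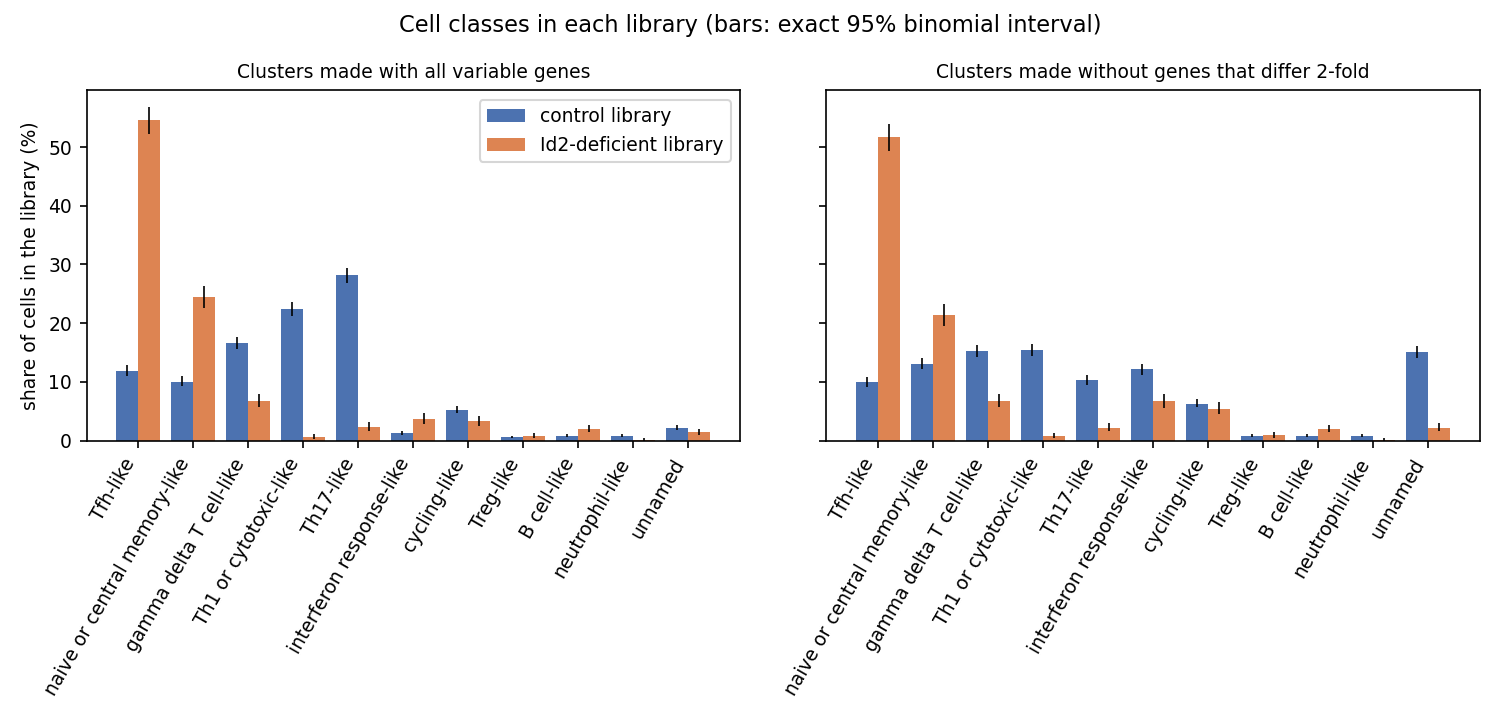
Share of each library's cells (y axis, percent) in each cell class (x axis) for the control and the Id2-deficient library, with exact 95% binomial intervals; left, clusters made with all variable genes, and right, without genes that differ 2-fold. Tfh-like cells are 11.9% and 54.5% at left and 10.0% and 51.6% at right.

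The libraries were then compared within the 4 clusters that held at least 100 cells of each. Id2 was lower in the Id2-deficient library in all 4, at 2.65 against 115 CPM in Tfh-like cluster 1, 7.01 against 70.3 CPM in the naive or central memory-like cluster 3, and 23.9 against 458 CPM in the γδ T cell-like cluster 4. In Tfh-like cluster 5, led by Pdcd1 and Rgs16, it gave 0 UMIs against 83.0 CPM, or at least 44.6-fold lower at a floor of 3 counts. Id3 was 124 against 15.8 CPM in cluster 4 and 283 against 175 CPM in cluster 1, but 133 against 106 CPM in cluster 3 and 228 against 226 CPM in cluster 5. Klf2 was lower in all 4, with log2 ratios of −0.67, −0.64, −0.69 and −2.38 in clusters 1, 3, 4 and 5. Mitochondrially encoded genes had medians of 0.91, 0.91, 0.91 and 0.92.

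Gene lists were taken within the same clusters. The Tfh list, which defines clusters 1 and 5 in part, had medians of −0.16, 0.04, 0.39 and 0.30 in clusters 1, 3, 4 and 5, and the glycolysis list −0.18, −0.06, −0.09 and 0.06. In the same order the fatty acid and cholesterol synthesis list had −0.01, −0.47 (−0.65 to −0.29), −0.25 and 0.44 (0.11 to 0.63). The Th1 and cytotoxic list had 0.08 and 0.27 in clusters 1 and 3, −0.43 (−0.67 to −0.16) in cluster 4 and −1.70 (−2.22 to −1.19) in cluster 5. There, in genes picked out after their values were seen, Ifng was −2.78 (−3.95 to −1.75), Cxcr6 −1.61 (−2.07 to −1.16) and Il7r −3.83 (−4.63 to −3.12), and Nkg7 gave 0 UMIs against 34.6 CPM. Ifng and Nkg7 rested on 37 and 30 control UMIs. Pdcd1 (0.02) and Bcl6 (0.18) were near alike in cluster 5, and Cxcr5 was 0.73. Whether its control part holds more cells other than Tfh cells was not tested, so these are not differences at a known matched state. Interferon response genes had medians of 0.26, 0.49, 0.86 and 0.01. With cells thinned to 1000 UMIs the Th1 median of cluster 5 was 0.09 over 3 measured genes, and the Id2 log2 ratio within cluster 3 was −4.92 and that within cluster 5 was −1.99, where the Id2-deficient cells were at the floor.

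The γδ T cell-like cluster was looked at gene by gene after its share had been seen, since γδ T cells are innate-like makers of interleukin 17 and the cells had been sorted for CD4. It held 816 control and 130 Id2-deficient cells, with median depths of 5625.5 and 7937.5 UMIs. Among genes with at least 50 UMIs in the cluster, Id3 was the highest in the Id2-deficient library, 7.89-fold higher (log2 ratio 2.98, 2.57 to 3.40). Il17f was 4.22-fold higher (log2 2.08, 1.73 to 2.42), with a UMI in 22.3% of Id2-deficient (15.5% to 30.4%) and 9.68% of control cells (7.74% to 11.9%). The interferon-induced GTPase gene Iigp1 (2.57) and Ifit1 (1.99), the cytokine receptor gene Il21r (2.06), the stress genes Hspa1b (2.23) and Hspa1a (2.07) and the lysosomal lipase gene Lipa (2.004) were also among the highest. Lower beside Id2 were Gzmb, a granule protease gene (−2.45, −3.24 to −1.75), Stmn2 (−2.78) and Arl6ip5 (−1.64). However, Trdc stood at 825 CPM in control and 1365 CPM in Id2-deficient cells of the cluster, and at least 3 Trdc UMIs were seen in 67.8% and 91.5% of cells. Stmn2 also led the Th17-like cluster made with all genes. The control part may thus hold more cells that are not γδ T cells, and whether these account for the lower genes was not tested. The neutrophil gene S100a8 was among the lowest too, with a UMI in 9.07% of control and 0% of Id2-deficient cells of the cluster, but other T-lineage cells showed it in 6.56% and 0.513%, and neutrophil-like cells numbered 41 and 2. Cd4 itself gave 23.1 CPM in control and 1.92 CPM in Id2-deficient cells of the cluster, the latter from 2 UMIs (log2 ratio −3.59, −6.65 to −1.71). Il17a was 19.4 and 36.4 CPM, but 23 of the 38 Id2-deficient UMIs lay in 1 cell. Il10, under that minimum, gave 0 control and 24 Id2-deficient UMIs, and 24 of these lay in 1 cell.

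**Figure D3:**
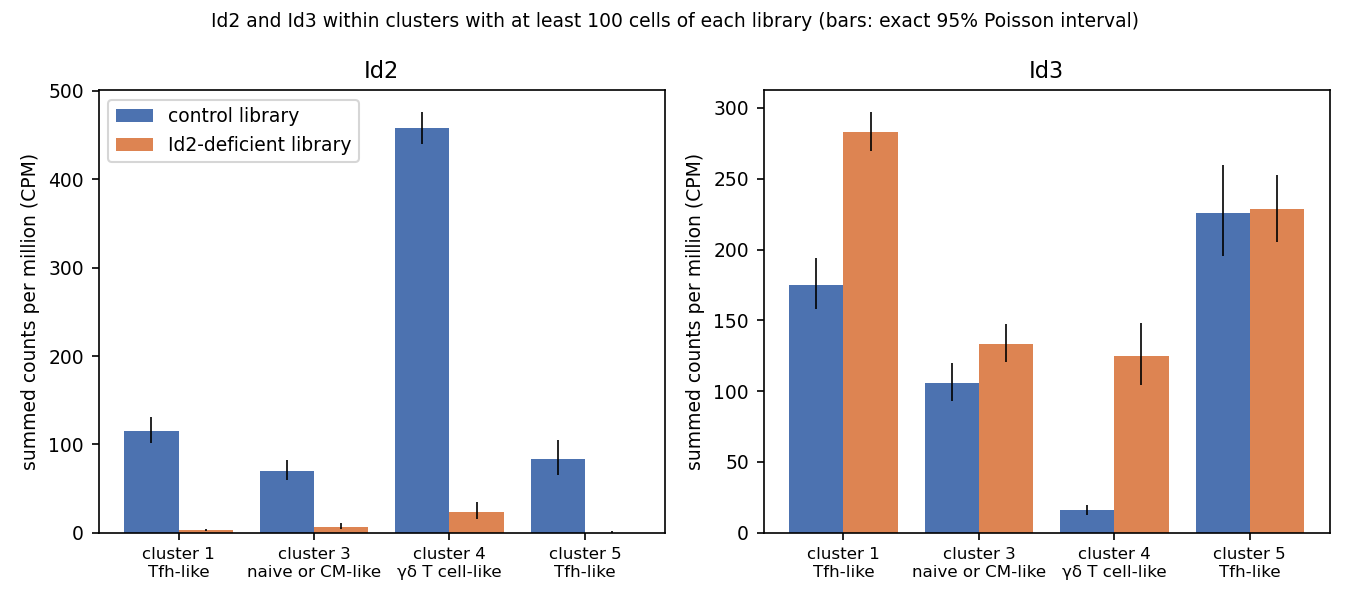
Summed CPM (y axis) of Id2 (left) and Id3 (right) in the control and the Id2-deficient cells of the 4 clusters (x axis) with at least 100 cells of each library; bars carry exact 95% Poisson intervals. Id2 is lower in the Id2-deficient library in all 4, and Id3 is 124 against 15.8 CPM in the γδ T cell-like cluster 4.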

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

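Of the tests in this part, those of recombination, of a damaged part of the T cells and of free Id2 RNA were chosen only after the results they measure had been seen; those of RNA quality, depth, mix of cell states, handling and shared barcodes were written down earlier.

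The cell filter left out 21.4% of Id2-deficient barcodes (19.7% to 23.0%) against 0.243% of control barcodes, a signal in data that the comparisons do not use. These Id2-deficient barcodes had a median of 25.8% mt- UMIs and 878 UMIs. B cell-like cells, which are not in the comparisons either, made up 1.97% of Id2-deficient cells (1.40% to 2.70%) against 0.833% of control cells (0.598% to 1.13%). Neither difference was tested across mice, and whether both libraries were filtered alike before deposit is not given in the sources used here.

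The Tfh list was higher and the Th1 and cytotoxic list lower in the Id2-deficient library, the direction in which loss of Id2, a brake on E proteins, would be a biological explanation. In the 4 clusters that hold 1650 Id2-deficient cells the upper bound of the Id2 ratio was at most 0.157, so cells without recombined Id2 can be few there. Id2 was already known to be 24.9-fold lower over all T-lineage cells. This outcome was therefore largely given beforehand and is no separate evidence on the cause. Depth was not decided by thinning to 1000 UMIs, where the list medians were 1.58 and −1.68, or 92.8% and 98.5% of their size. The ratios already divide by each library's total, and thinning mainly gives each cell equal weight, so little shrinkage was possible. Lower RNA quality stays open: among cells with 2% to 3% mt- UMIs the medians were 0.85 and −0.91 (49.8% and 53.1%), but this window kept 43.2% of control and 8.95% of Id2-deficient Tfh-like cells, so it shifts the mix of states and decides nothing on RNA quality. How far a different mix of cell states accounts for the list differences stays open too. Tfh-like cells made up 11.9% of control and 54.5% of Id2-deficient cells, and Th1 or cytotoxic-like cells 22.4% and 0.675%, so the mix differed. Within clusters the list medians were 0.18 and −0.37, which is 11.5% and 52.6% of the value the same genes have over all cells. Within clusters made without differing genes 26.5% and 21.1% were kept. Clusters rest in part on genes of these lists, which can itself shrink differences within them. The Th1-like and Th17-like clusters also hold too few Id2-deficient cells to compare.

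Mitochondrially encoded RNA was higher in the Id2-deficient library in every T-lineage cluster compared. A library-wide difference in handling or RNA quality fits this: in B cell-like cells, to which the Cre is not directed, the log2 ratio of the mt- share was 0.75 (0.70 to 0.80), against 1.26 in T-lineage cells. The tables argue against a more damaged part of the T cells alone, since under the stricter cell filter the list median was 0.94, or 86.0% of its size. The part of the T cell difference beyond that of B cell-like cells has no test here, and a biological share in it stays open.

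Clusters that hold mostly control cells (Th17-like and Th1-like) held some Id2-deficient cells with at least 3 Id2 UMIs, and no biological explanation was tested for them. Free Id2 RNA would give such cells alike everywhere, but they made up 19.0% there (11 of 58; 9.87% to 31.4%) and 0.657% of other T-lineage cells (12 of 1827; 0.340% to 1.14%). Barcodes shared with the control library account for 0 of the 11. Whether Id2 was left unrecombined in these cells stays open. Their Id2 level was 1.41 times that of Id2-positive control cells of the same clusters (1.12 to 1.77), at 901 against 637 CPM. The explanation named a level within the control range, and the result named against it was a level well below that of control cells. Neither was met, and 11 cells picked for their Id2 UMIs decide little.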

How the results depend on the processing

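All of the alternatives here are values beside the first analysis and none adds tests; those with cells of 2% to 3% mt- UMIs, with the T cell receptor gate, without the γδ T cell-like cluster, with averages within clusters made without differing genes, and with class shares under other filters and doublet treatments were chosen after the data were seen. No paired analysis was possible because each genotype has 1 library and the shared replicate number joins no pair. Of the values that answer the comparisons, 121 kept their direction and size, 66 kept their direction with another size and 5 had another direction; of the other values these were 1318, 509 and 34. Unless a reason is given, the cause was not tested.

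Among cells with 2% to 3% mt- UMIs, log2 ratios were Id2 −3.83, Stat4 −0.11, Izumo1r −0.0375, Nt5e −0.51, Tcf7 −0.28, Ldha 0.0826, Timm23 0.0627, Decr1 −0.43, Birc5 3.98, Stmn1 3.03, Ube2c 4.36, Ly6c2 0.53, Slfn5 −0.30, Pmaip1 0.57 and Prdx4 0.10. List medians there were Th1 and cytotoxic −0.91, Tfh 0.85, naive and central memory −0.18, glycolysis 0.0826, oxidative phosphorylation, nuclear encoded, 0.0678, cell cycle 2.996, and immediate early and dissociation stress −0.0175. The window itself changes the mix of cell states, keeping 3.46% of control and 42.9% of Id2-deficient cycling cells.

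Averaged within clusters, log2 ratios were Nt5e −0.49, Tcf7 −0.0167, Decr1 −0.33, Ifi27l2a −0.0358, Cd28 −0.11 and Pdcd1 −0.36, and list medians Th1 −0.37, Tfh 0.18, naive and central memory 0.14, apoptosis and survival −0.0032 and γδ T cell 0.47. Within clusters made without differing genes the Id2 log2 ratio was −4.32, with Nt5e −0.22, Decr1 −0.26, Pdcd1 −0.29 and Pmaip1 0.0596, and list medians Th1 −0.11, Tfh 0.40, Treg −0.0123, naive and central memory 0.18, apoptosis and survival −0.00096 and γδ T cell 0.0123. Fewer list members are measured within clusters.

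With other cells or totals, the nuclear-encoded oxidative phosphorylation median was −0.26 with no cell filter, −0.19 with the stricter filter, −0.30 centred on the median gene, −0.15 with totals without mt- and ribosomal protein genes, −0.26 with equal weight per cell, −0.27 thinned to 1000 UMIs and −0.18 as a mean. The Th17 median was 0.27 with no filter and 0.42 thinned, and the Tfh median 1.51 with the stricter filter, 1.58 with equal weight per cell and 1.58 thinned. The naive and central memory median was 0.83 and the glycolysis median −0.0102 with totals without mt- and ribosomal protein genes, and the former 0.65 as a mean. Id2 was −4.34 with equal weight per cell, and Id1 −0.0275 with all cell classes. Thinned, Id2 log2 ratio within cluster 3 was −4.92 and within cluster 5 −1.99, the latter set by the floor of 3 counts, and the Th1 median within cluster 5 was 0.0896 over 3 genes.

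Differences in the share of cells with a UMI depend on depth, and those of Id2, Ifng and Cxcr5 grew with it. In percentage points, the difference in Id2-positive cells was −63.6 unthinned, −40.6 thinned to 2000 and −13.1 thinned to 500 UMIs. In the same order the difference in Ifng-positive cells was −6.96, −3.97 and −1.25 and the difference in Cxcr5-positive cells 25.0, 10.4 and 3.37, and unthinned the difference in Il17a-positive cells was −0.858.

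Class share differences, in percentage points for Tfh-like, Th1-like, Th17-like and naive or central memory-like cells in that order, were: no cell filter, 29.9, −2.35, −22.8 and 11.2; stricter filter, 34.5, −18.2, −24.2 and −2.42; doublet calls kept, 39.5, −19.1, −2.03 and −3.63; highest doublet scores removed, 30.2, −17.9, −23.6 and 10.3. With another seed the first 3 were 37.8, −18.8 and −27.9. At resolution 0.5 Th1-like, Th17-like and naive or central memory-like cells gave −18.7, −29.1 and 16.9, and at resolution 1.2 Tfh-like, Th17-like and naive or central memory-like cells gave 10.6, −6.69 and 0.214. Without cell cycle genes Th1-like cells gave −17.3 and naive or central memory-like cells 11.1, and without differing genes Th1-like −14.6, Th17-like −8.08, interferon response-like −5.45 and naive or central memory-like 8.31. No cluster was named Th17-like without cell cycle genes, Treg-like with no cell filter, with the highest doublet scores removed or with another seed, or interferon response-like at resolution 0.5, so these have no value.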

Other observations

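The values in this part were looked at only after the results had been seen, and no tests were run on them.

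Among the 802 Id2-deficient cells of Tfh-like cluster 1, 13 had at least 3 UMIs of Trdc, the constant gene of the T cell receptor δ chain (1.62%, 0.866% to 2.76%), against 1 of 418 control cells. In these 13 cells Trdc stood at 1492 CPM, against 1.98 CPM in the other 789. They also carried the αβ receptor genes Trac (789 against 1229 CPM), Trbc1 (1200 against 1461 CPM) and Trbc2 (2541 against 2810 CPM), and Cd4 (281 against 275 CPM). Tcrg-C1, Tcrg-C2 and Tcrg-C4 gave 0 UMIs in the 13 cells, against 6.83, 8.26 and 3.95 CPM in the other 789. The upper 95% bounds of the log2 ratio were 2.62, 2.33 and 3.46. The 13 cells are thus too shallow to show less of these genes than the other cells of the cluster. A comparison with the level in the γδ T cell-like cluster was not made.

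In the γδ T cell-like cluster itself, at least 3 Trdc UMIs were seen in 67.8% of control and 91.5% of Id2-deficient cells, and Trdc stood at 825 and 1365 CPM. Over all T-lineage cells Cd4 stood at 163 and 251 CPM, Trac at 565 and 1001 CPM and Trdc at 150 and 132 CPM. The nuclear noncoding RNA Malat1 was higher in the Id2-deficient library (log2 ratio 0.58), as were Neat1 (0.48), Kcnq1ot1 (1.24) and Xist (1.22). Within clusters 1, 3, 4 and 5 the ratios were smaller, at 0.09, 0.11, 0.36 and 0.22 for Malat1 and 0.83, 0.69, 0.83 and 0.90 for Xist. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty gave 0 UMIs in both libraries. Within 10 Mb of Id2, 7 of 54 measured genes differed at least 2-fold, and elsewhere 1212 of 11121 did.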
